A study of Homo sapiens with 6 samples.

How the data were processed

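The study measured total RNA of long-term cultured human pancreatic islet cells on 6 Affymetrix Human Transcriptome Array 2.0 arrays, 3 from cultures given DMSO and 3 from cultures given ISX. The deposited values are log2 expression values that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes, at the level of an alternative splicing analysis and read out in Transcriptome Analysis Console 2.0, per the labels. No other step on the deposited values is stated in the sources used here. They were used as they are, with no further normalization, and the arrays have a single colour, so there is no dye effect.

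The table holds 914585 features, among them 571609 probe set regions, 337791 exon junctions and 1530 control features. Regions and junctions were named by the symbols of the platform annotation: 384659 regions had 1 symbol, 22452 had several and 164498 had none. No gene was named from a feature with several symbols. The symbols are old, and the names of the annotation are kept. No genome was used here, so coordinates are not given. Features of the Y chromosome and of XIST, 3655 in number, were left out throughout.

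The value of a gene was the median over its regions with 1 symbol, which gave 22022 genes with a median of 14 regions each. Genes were tested with limma 3.58.1 in R 4.3.3, with the pair as a block and treatment as the effect, an intensity trend in eBayes and Benjamini-Hochberg adjustment. No filter on dim genes was applied. The block is part of the main test because the series text describes the samples as 3 pairs. The numbers were checked on the data: deviations from the group means correlated at 0.715, 0.658 and 0.511 between arrays of the same number and at -0.561 to -0.030 between arrays of different numbers. With the block, p-values measure how the ISX minus DMSO difference varies between these 3 pairs, with variances moderated over genes. Whether a pair is 1 donor is not stated in the labels, so they may not cover the spread between donors.

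Gene lists were tested with camera at the preset inter-gene correlation of 0.01 and adjusted over 30 lists, of which 567 of 604 genes were measured. The lists were islet hormones, islet transcription factors, glucose sensing and proinsulin processing, secretory granule and exocytosis, neuronal genes, MEF2 and class IIa HDAC genes, immediate early genes, G1/S and replication, G2/M and mitosis, collagen and matrix, mesenchymal and contractile genes, TGF-beta response, epithelial junction and keratin genes, duct, acinar, endothelial, leukocyte and Schwann cell markers, unfolded protein and amino acid response, NRF2, aryl hydrocarbon receptor, metallothioneins, cholesterol synthesis, glycolysis and hypoxia, fatty acid oxidation and PPAR, oxidative phosphorylation, interferon response, inflammatory cytokines, p53 and senescence, and Notch and Wnt feedback. BTG2 is in 2 of them and every other gene in 1. Unequal change within genes was tested with limma's diffSplice on 380509 regions of the 18594 genes with at least 3 regions.

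Named genes followed a rule fixed before the data were examined, as were the lists and all alternatives not described as later choices. The rule takes 12 genes of islet function, proliferation and matrix in any case, the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign in 3 pairs, up to 4 members of each list with the smallest p among those past the threshold adjusted over the list alone (otherwise up to 2, as values), and the 6 genes with the smallest p for unequal regions. It gave 136 genes with a value. Of the genes taken in any case, 1 is not reported here. Of the 118 that passed, 43 also passed without the pair block and 85 passed without each of the 3 pairs in turn.

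The tests were tested on simulated data. For the comparison of ISX with DMSO over 22022 genes, the gene test recovered 67.2% of genes changed by 0.5 (log2). It recovered 100% of those changed by 1 or 2, with 24 false calls in all. The recovered genes were 45 of 67, 67 of 67 and 66 of 66. In this simulation the gene test thus had a larger share of false calls among its calls than the adjusted p threshold of 0.05. Without the block it recovered 2.99%, 58.2% and 93.9%, with 1 false call. The list test, over the same 22022 genes, recovered 10 of 10 lists shifted by 0.3 with 0 false calls, where genes were drawn independently. The region test, on 3000 genes with 1 region changed by 2 in 200 of them, recovered all 200 genes and regions, but 60 of 260 called genes and 273 of 473 called regions were false, 209 of the regions in unchanged genes. Where regions of a gene shared variance, 198 genes and 200 regions were recovered and 8 genes and 124 regions were false. With equal spread of all regions of a gene, 12 of 212 genes and 91 of 291 regions were false, 20 of the regions in unchanged genes. With the same contrast and a variance for each region, 200 regions were recovered with 64 false in the first of these settings and 143 false in the last. On region minus gene median with a variance for each region, 159 regions were recovered with 6 false in the first.

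Alternatives were no block, the block as a random effect, equal array medians, quantile normalization, a filter at the 40th percentile of genes, the mean over regions, junctions added, other eBayes settings, array weights, a plain paired test, other thresholds, an estimated list correlation, fry, a filter on dim regions and leaving out each pair. Leaving out regions with duplicated values, limma on the contrast of diffSplice (region minus mean of the other regions) with a variance for each region, and limma on region minus gene median with a variance for each region were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.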

Results

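Long-term cultures of human pancreatic islet cells, kept for 8 to 14 months, were given isoxazole (ISX, a small molecule) at 20 µM or its vehicle, dimethyl sulfoxide (DMSO), for 7 days. Medium and compound were renewed on day 4. RNA of 3 DMSO cultures and 3 ISX cultures was hybridised to 6 single-colour arrays, each of which reads probe set regions (exons or parts of them) and exon junctions. The cultures formed 3 pairs of 1 DMSO and 1 ISX culture, numbered 1 to 3. Gene values were RMA log2 values, and 22022 genes were tested. The median gene lay between 6.30 and 6.42 on the 6 arrays, and the number of arrays limits the precision. The comparison of ISX with DMSO shows how the expression of genes, of gene groups and of regions within genes differed after ISX treatment.

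With ISX, 11 of 27 neuronal genes, 9 of 30 genes of secretory granules and 8 of 17 epithelial genes rose, and 14 of 29 genes of DNA replication and 9 of 33 of mitosis fell. These 5 lists passed camera with a preset correlation. None did with an estimated one, which leaves few degrees of freedom (adjusted p = 0.346 to 0.661 with an estimated correlation). That correlation was 0.321 for replication and 0.953 for mitosis, against the preset 0.01, so their preset p-values may be far too small. *INA*, a neuronal intermediate filament gene, had the largest rise, by 3.70 ± 0.12 (log2, SE, n = 3 pairs), which is 13.0-fold. *CCL11*, a chemokine gene, had the largest fall, with a log2 change of -2.33 ± 0.48 and a call that was lost without pair 1. In all, 3040 of 22022 genes changed at an adjusted p under 0.05 by limma, 2147 of them higher and 893 lower with ISX. Of these, 523 changed at least 2-fold, 506 of them higher and 17 lower. Each of the 3040 genes moved the same way in all 3 pairs, which the threshold nearly requires with so few pairs.

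The other 11 of the 12 genes with the largest rises included several known from neurons. *CNTN1*, an adhesion molecule of axons, rose by 3.27 ± 0.17, *LPPR4* (now PLPPR4), a membrane protein of neurons, by 3.12 ± 0.16, and *FRRS1L*, which associates with glutamate receptors, by 2.79 ± 0.09. *STMN2*, a regulator of neuronal microtubules, rose by 3.00 ± 0.58, with 0.82 in pair 2 against 3.74 and 4.45 in pairs 1 and 3, and its call was lost without pair 1. The organic anion transporter gene *SLCO4C1* rose by 3.63 ± 0.34 and the cell surface proteoglycan gene *GPC3* by 2.95 ± 0.17 (1.68 with the mean over regions as gene value). *FAM70A* (now TMEM255A), the transcription factor gene *NFE2L3*, *TMEM130*, *CAPN6* and *CYTL1* rose by 2.75 to 3.10. The adjusted p of these 12 genes by limma ran from 2.99e-05 for *INA* and *FRRS1L* to 0.0145 for *STMN2*.

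**Figure D1:**
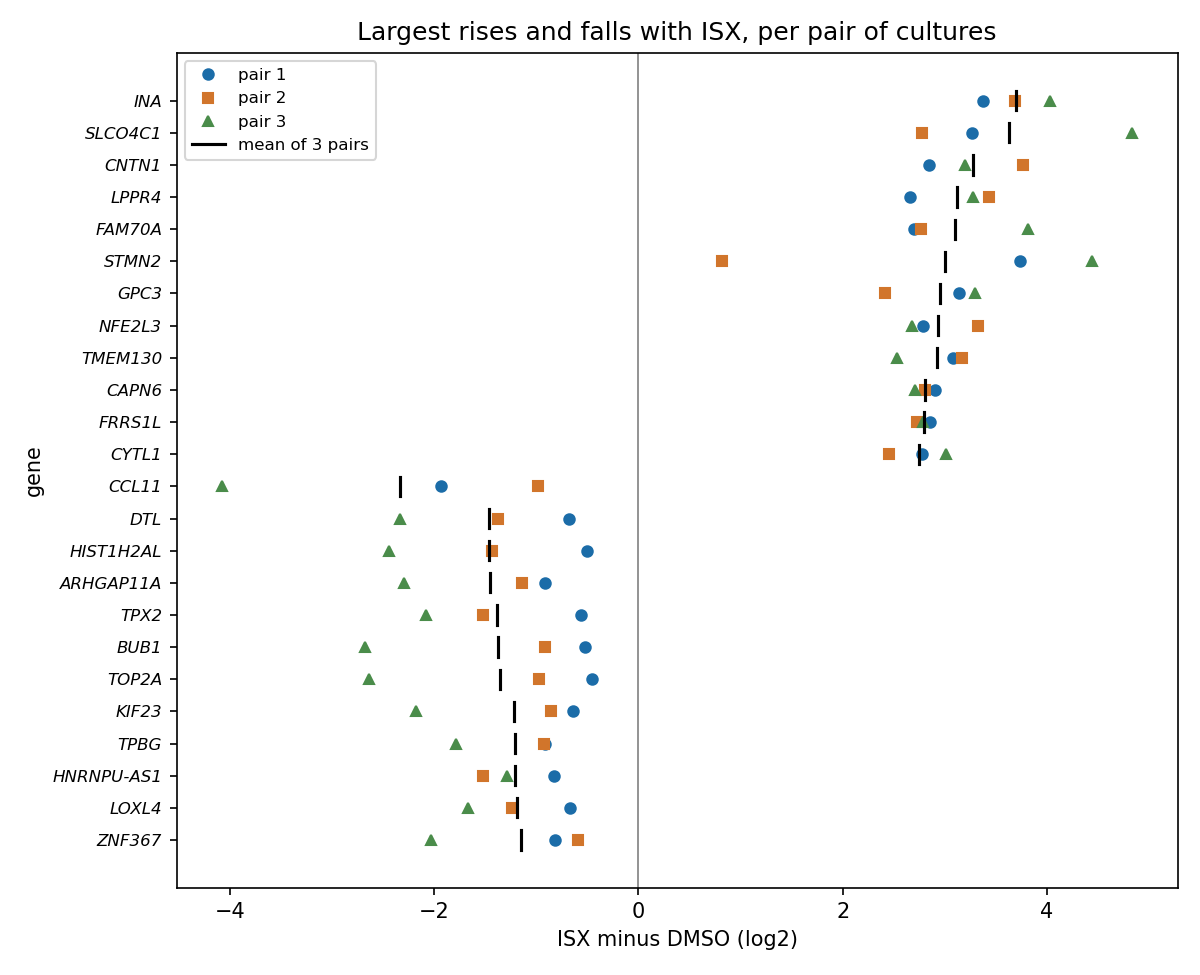
Change of each gene with ISX (x axis, ISX minus DMSO, log2 units) for the 12 largest rises and the 12 largest falls (y axis). Symbols show the 3 pairs and the bar their mean: *INA* lies between 3.38 and 4.03 and *CCL11* between -4.08 and -0.98.

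Among the 12 genes with the largest falls were several that act in mitosis. *TPX2*, a spindle assembly factor, had a change of -1.39 ± 0.24, *KIF23*, a motor of cytokinesis, -1.22 ± 0.26, *BUB1*, a spindle checkpoint kinase, -1.37 ± 0.36, and *TOP2A*, which untangles replicated DNA, -1.36 ± 0.36. *DTL*, an adaptor of a ubiquitin ligase active in S phase, fell by 1.46, and *ARHGAP11A* by 1.45. *ZNF367* fell by 1.15, *TPBG*, a cell surface glycoprotein, by 1.21, and *LOXL4*, a lysyl oxidase of the extracellular matrix, by 1.19. *HIST1H2AL* (now H2AC16) fell by 1.46, an uncertain value, since histone genes share nearly identical sequence. *HNRNPU-AS1* fell by 1.21 and is uncertain too: the name is now listed as an older name of *HNRNPU*, whose own regions had a change of -0.16 with an adjusted p of 0.160 by limma. In pair 3, *TPX2*, *KIF23*, *BUB1* and *TOP2A* fell by more than 2 on the log2 scale, whereas in pair 1 the changes ran from -0.64 to -0.45. The calls of *HIST1H2AL*, *BUB1* and *TOP2A* were lost without pair 2 and that of *ZNF367* without pair 1. With the mean over regions as gene value, *BUB1*, *TOP2A* and *ZNF367* were not called either (adjusted p = 0.0628 to 0.0791), and the changes of *ZNF367*, *HIST1H2AL* and *TPBG* were -0.34, -0.71 and -0.63. Without pair 3 the changes of *CCL11*, *HIST1H2AL*, *KIF23*, *BUB1*, *TOP2A* and *ZNF367* were -1.46, -0.97, -0.75, -0.72, -0.72 and -0.70.

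Without the pair as a block 634 genes passed, 581 higher and 53 lower, including 43 of the 118 named genes with a call, and without pair 1, 2 or 3 the count was 1825, 1929 and 1930. With the array medians set equal, 1890 genes were higher and 1564 lower, with quantile normalization 2001 were higher and 1329 lower, and with the mean over regions 5220 genes passed, 9 of the 118 named genes lost their call and 29 had a change that differed by over 1.5 times.

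Among the genes of islet identity, hormones and transcription factors did not pass the test, while 9 of 30 genes of secretory granules rose. None of the 6 measured islet hormones and none of the 20 measured islet transcription factors passed, over all genes or adjusted over the list alone. Of the 30 genes of secretory granules and exocytosis 15 rose when adjusted over the list alone, with a median change of 0.30. *SCG2* (secretogranin II) rose by 2.71 ± 0.23, *SYT1*, a calcium sensor of vesicle release, by 2.11 ± 0.15, *PTPRN*, a granule membrane protein, by 1.55 ± 0.12, and *SCG5*, the chaperone of prohormone convertase 2, by 1.47 ± 0.07. By camera this list shifted upward relative to the other genes (adjusted p = 2.83e-07), with adjusted p = 0.346 with an estimated correlation.

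The hormone genes differed widely between the pairs. *GCG* (glucagon) stood at 10.1 and 9.41 in DMSO cultures 1 and 2 and at 3.53 in DMSO culture 3, and its changes were -0.91, -0.63 and 0.44 in pairs 1 to 3. Its mean change of -0.36 ± 0.23 had an adjusted p of 0.337 by limma, and without pair 3 a change of -0.77 had an adjusted p of 0.00241. Without pair 1 and without pair 2 the changes were -0.09 and -0.23 (adjusted p = 0.860 and 0.688 by limma). *SST* (somatostatin) had changes of 0.04, 0.14 and -2.07, and *IAPP* (islet amyloid polypeptide) of 0.36, 2.11 and 0.10. Without pair 3 the change of *SST* was 0.09, and without pair 2 that of *IAPP* was 0.23. *INS* (insulin) carried no region of its own in the annotation used here. *NEUROD1*, *PDX1*, *MAFA* and *ISL1*, transcription factors of islet endocrine cells, had changes of 0.05, 0.09, 0.06 and 0.10, with adjusted p of 0.568 to 0.839 by limma and changes of -0.04 to 0.20 in the alternative settings. *MNX1* (-0.23) and *PAX4* (-0.18) had the smallest p among the islet transcription factors, and changes of -0.05 and -0.11 with the mean over regions. *CHGA* (chromogranin A) had a change of -0.09 (-0.16 with the mean over regions, -0.03 without pair 3) and *CHGB* (chromogranin B) of 0.58, with adjusted p of 0.514 and 0.103. The change of *CHGB* was 0.23 without pair 3 (adjusted p = 0.233), and 0.30 with the mean over regions, where it passed (adjusted p = 0.0448).

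Of 20 genes of glucose sensing and proinsulin processing 5 rose, 6 adjusted over the list alone, with a median change of 0.20 (0.13 with the mean over regions, 0.12 without pair 2). *PCSK1*, a prohormone convertase, rose by 1.21 ± 0.16, *CPE*, the carboxypeptidase that trims prohormones, by 0.61 ± 0.07, the calcium channel gene *CACNA1A* by 0.85 ± 0.08 and *ENTPD3*, a cell surface nucleotidase, by 1.19 ± 0.18. The list had an adjusted p of 0.000994 by camera and adjusted p = 0.346 with an estimated correlation.

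**Figure D2:**
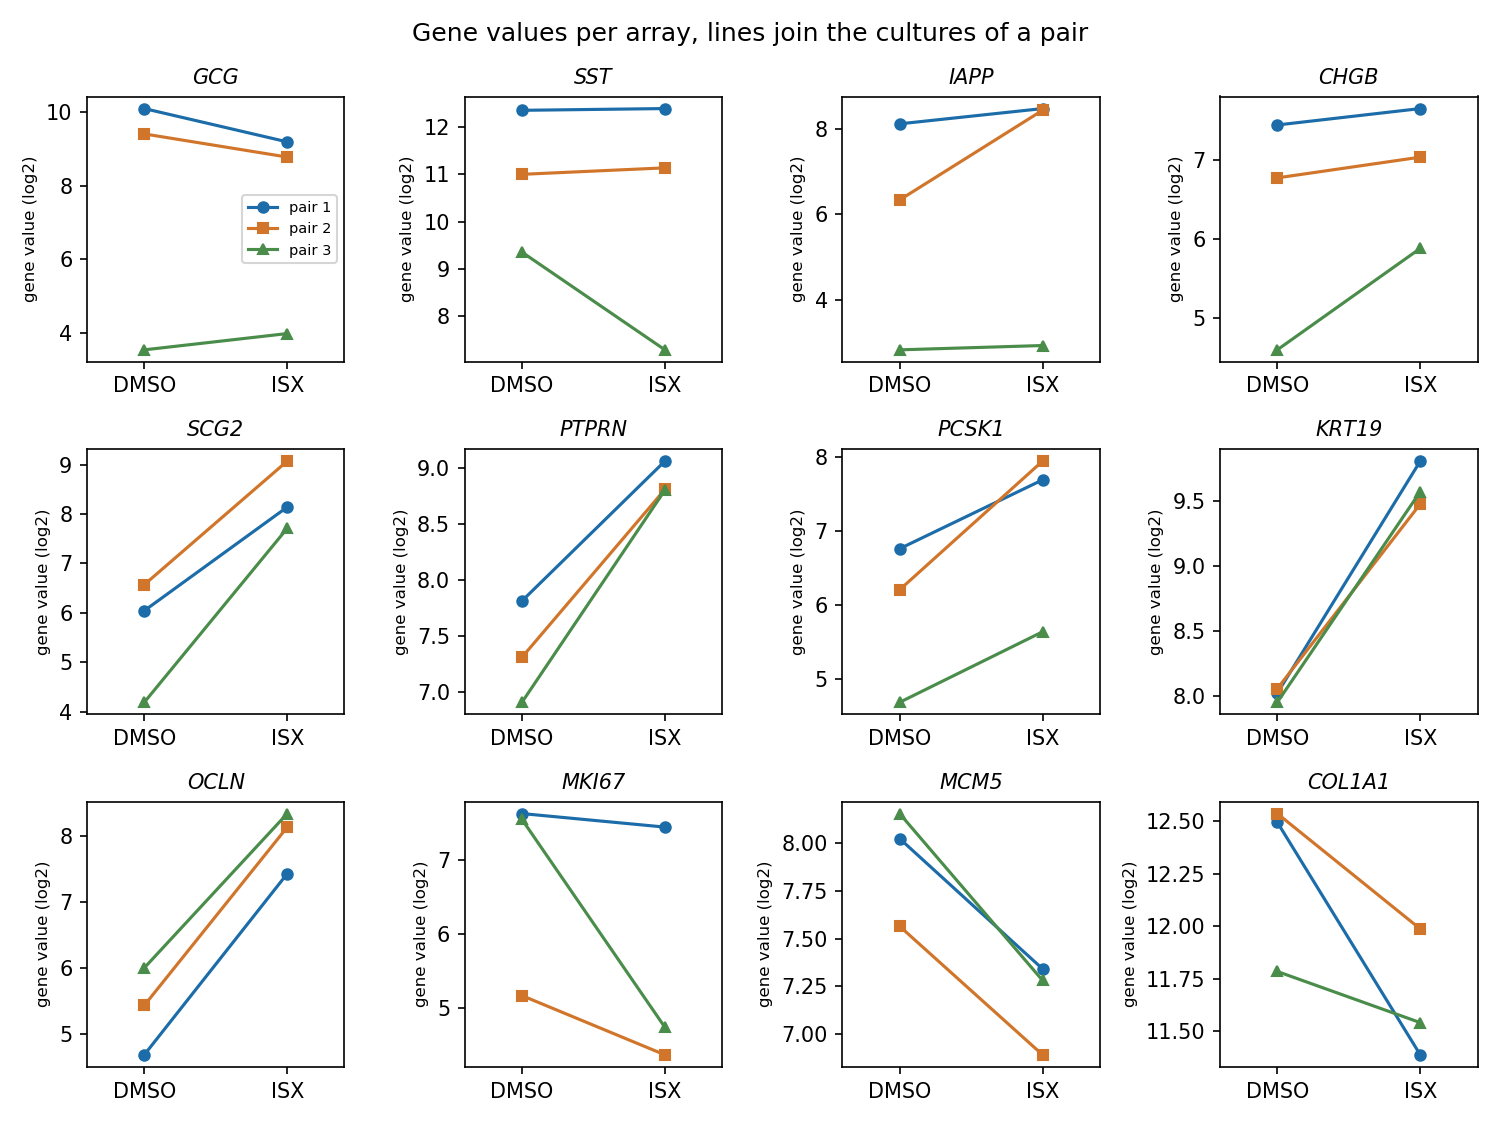
Gene value (y axis, log2, a separate scale in each panel) in DMSO and ISX cultures (x axis) for 12 genes, with lines that join the 2 cultures of a pair. *SCG2*, *PTPRN*, *KRT19* and *OCLN* were higher with ISX in all 3 pairs, *MCM5* and *COL1A1* were lower in all 3, and *GCG* stood at 3.53 and 3.97 in pair 3.

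Of 27 neuronal genes 11 rose, and adjusted over the list alone 14 rose and 1 fell, with a median change of 0.34 (0.93 without the dimmest 40% of genes, 0.16 with the mean over regions). *NEFL*, a neurofilament, rose by 2.19 ± 0.13, *CRMP1*, which acts in axon guidance, by 1.46 ± 0.07, and *MAP2*, a microtubule protein of dendrites, by 1.39 ± 0.11. Camera gave the list an adjusted p of 5.95e-06 and adjusted p = 0.346 with an estimated correlation. Of 17 epithelial junction and keratin genes 8 rose, also adjusted over the list alone, with a median change of 0.24 that was 0.44 without the dimmest 40% of genes and 0.11 with the mean over regions. They included *OCLN* (occludin of tight junctions) by 2.59 ± 0.11, *CDH3* (P-cadherin) by 1.71 ± 0.10, *JUP* (plakoglobin) by 1.09 ± 0.08 and *CLDN7* (a claudin) by 0.78 ± 0.10 (*OCLN*, *JUP* and *CLDN7* by 1.52, 0.59 and 0.46 with the mean over regions). This list had an adjusted p of 0.00128 by camera and adjusted p = 0.346 with an estimated correlation.

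Markers of other cell types moved with these groups in part. Of 12 duct markers *KRT19*, a keratin of duct cells, rose by 1.60 ± 0.08 (1.03 with the mean over regions) and *SOX9*, a transcription factor of duct cells, by 0.64 ± 0.08, and *MUC1*, a mucin, fell by 0.43, a call lost without pair 1 and without pair 3. The count adjusted over the list alone was also 2 higher and 1 lower, and the list did not pass camera (adjusted p = 0.0986). None of 21 acinar markers passed over all genes or adjusted over the list alone (median -0.15, adjusted p = 0.0796 by camera; -0.07 with the mean over regions and -0.10 without pair 2), and *CTRB2* and *GP2* had changes of -0.22 and -0.24 (-0.14 and -0.11 with the mean over regions). Of 13 endothelial markers *FLT1* and *KDR*, receptors for vascular endothelial growth factor, rose by 0.72 and 0.71 and *TEK*, an angiopoietin receptor, fell by 0.75, as also adjusted over the list alone. Of 15 leukocyte and macrophage markers *CD74*, which escorts major histocompatibility complex class II proteins, rose by 0.71 (0.43 with the mean over regions) and *CD68*, a lysosomal protein, fell by 0.70, also adjusted over the list alone. Of 7 Schwann cell markers *ERBB3* rose by 0.60, also adjusted over the list alone. The calls of *KDR* and *CD74* were lost without pair 1 or pair 2, and that of *ERBB3* without pair 1 or pair 3. The endothelial, leukocyte and Schwann cell lists had adjusted p of 0.973, 0.899 and 0.887 by camera, and the endothelial list had a median of -0.06 (-0.10 without pair 1, -0.01 without pair 2) and a mean of 0.02.

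Of 27 collagen and matrix genes 8 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone, with a median change of -0.22. *COL1A1*, the main fibrillar collagen chain, fell by 0.63 (SE 0.15, adjusted p = 0.0294 by limma), a call that was lost without pair 1 (change -0.40) and without pair 2. *LOX* and *LOXL2*, which cross-link collagen, had changes of -0.44 and -0.43, and *FBN1* (fibrillin) of -0.42. *TNC*, a matrix glycoprotein, rose by 0.90. The list had an adjusted p of 0.0280 by camera and adjusted p = 0.747 with an estimated correlation, and the call ended without pair 1 (median -0.12, adjusted p = 0.239), without the pair block (adjusted p = 0.0589), with quantile normalization (adjusted p = 0.0758) and with the mean over regions (adjusted p = 0.0814). Of 27 mesenchymal and contractile genes 7 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone. *DES* (desmin) rose by 1.25, *CNN1* (calponin) by 0.50 and *CDH11* (a cadherin) by 0.46 (not called without pair 2), and *FAP*, a protease of activated fibroblasts, fell by 0.69. The list did not pass camera (adjusted p = 0.136), but did without pair 1 (adjusted p = 0.0227) and with the mean over regions (adjusted p = 0.0425).

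Of 29 genes of G1/S and replication 14 fell, 18 adjusted over the list alone, with a median change of -0.45. *MCM5* and *MCM4*, parts of the replicative helicase, had changes of -0.74 ± 0.08 and -0.87 ± 0.16, *CDC6*, which loads it, of -1.13 ± 0.19, and *CHAF1A*, a histone chaperone, of -0.67 ± 0.10 (*CDC6* -0.63 and *MCM4* -0.55 with the mean over regions). Camera gave the list an adjusted p of 2.71e-08 and adjusted p = 0.399 with an estimated correlation, which was 0.321 against the preset 0.01. Of 33 genes of G2/M and mitosis 9 fell and 25 fell adjusted over the list alone, with a median change of -0.77. *CDC20* and *CDC25C*, which drive mitosis, fell by 0.73 and 0.58, calls that were lost without pair 2 and without pair 3, and for *CDC25C* with the mean over regions (adjusted p = 0.0793). The median of this list was -0.18, -0.51 and -1.87 in pairs 1 to 3, and -0.33 without pair 3. It had an adjusted p of 6.92e-08 by camera and adjusted p = 0.661 with an estimated correlation, which was 0.953. Both cell division lists may therefore have preset p-values that are far too small. *MKI67*, a marker of cycling cells, had a change of -1.27 ± 0.42 with an adjusted p of 0.0947 by limma. Without pair 3 its change was -0.49 (adjusted p = 0.131) and without pair 1 it was -1.81 (adjusted p = 0.0479).

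Of 22 interferon response genes 11 rose, and 13 rose and 1 fell adjusted over the list alone, with a median change of 0.49. *USP18*, *IFI6*, *IFI44L* and *BST2* rose by 1.44 ± 0.12, 1.35 ± 0.10, 1.22 ± 0.11 and 0.98 ± 0.10 (*USP18* by 0.95 with the mean over regions). The list had an adjusted p of 1.49e-06 by camera and adjusted p = 0.346 with an estimated correlation. Of 8 metallothioneins, small metal-binding proteins, 5 rose, and 5 rose and 1 fell adjusted over the list alone, with a median change of 0.58 (0.34 with the mean over regions). *MT1F* rose by 1.29 ± 0.11, *MT1A* by 1.26 ± 0.16, *MT1H* by 1.05 ± 0.17 and *MT1G* by 0.54 ± 0.10 (*MT1A* and *MT1H* by 0.78 and 0.33 with the mean over regions), and the single genes are uncertain because their sequences are nearly identical. The call of *MT1G* was lost without pair 1 and without pair 3. Camera gave the list an adjusted p of 0.00136 and adjusted p = 0.462 with an estimated correlation.

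Of 19 TGF-beta response genes 9 rose, and 11 rose and 1 fell adjusted over the list alone, with a median change of 0.26. *ANKRD1*, a muscle ankyrin repeat protein, rose by 1.97 ± 0.18, *WISP1* (now CCN4), a matricellular protein, by 0.71 to 1.43 in the 3 pairs, and *ID1* and *SMAD6*, targets of bone morphogenetic protein signals, by 0.83 ± 0.10 and 0.67 ± 0.09 (*SMAD6* by 0.42 with the mean over regions). The list had an adjusted p of 1.89e-05 by camera and adjusted p = 0.346 with an estimated correlation. Of 14 fatty acid oxidation and PPAR genes 5 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. *UCP2*, a mitochondrial carrier, rose by 2.11 ± 0.09 (1.39 with the mean over regions), *PPARGC1A*, a coactivator of mitochondrial genes, by 0.73 to 1.17 in the 3 pairs and *CPT1A*, the entry enzyme of fatty acid oxidation, by 0.46 ± 0.08, and *ANGPTL4*, an inhibitor of lipoprotein lipase, fell by 0.53. Camera gave the list an adjusted p of 0.00348 and adjusted p = 0.346 with an estimated correlation, and without the dimmest 40% of genes a median of 0.11 and an adjusted p of 0.288.

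Of 22 Notch and Wnt feedback genes 4 rose and 5 rose adjusted over the list alone, with a median change of 0.12 (0.06 with the mean over regions, 0.03 without pair 1): *LGR5*, a receptor for R-spondins, by 1.82 ± 0.15, *DKK2*, a secreted Wnt modulator, by 0.78, *JAG1*, a Notch ligand, by 0.55 and *AXIN2* by 0.40. By camera this list had an adjusted p of 0.0330, with adjusted p = 0.382 with an estimated correlation, and its call ended without pair 1 or pair 3 and without the pair block (adjusted p = 0.0589). Of 22 oxidative phosphorylation genes 1 fell, *NDUFS3* by 0.28, and none passed adjusted over the list alone. *NDUFV1* had a change of -0.22, and passed with the mean over regions and with equal array medians (adjusted p = 0.0342 and 0.0458). With a median change of -0.10 the list had an adjusted p of 0.0319 by camera and adjusted p = 0.382 with an estimated correlation, and its call ended without pair 3 and with the mean over regions (adjusted p = 0.0699). Of 5 aryl hydrocarbon receptor genes *TIPARP* and *CYP1B1* fell by 0.35 and 0.50, *CYP1A1* had a change of -0.31 (-0.20 with the mean over regions), and all 3 were lower adjusted over the list alone. The median of this list was -0.31, and -0.18 with the mean over regions. This list had an adjusted p of 0.0493 by camera and adjusted p = 0.399 with an estimated correlation, and its call ended without pair 1 or pair 3 and without the pair block (adjusted p = 0.0585). Without the dimmest 40% of genes none of these 3 lists passed. The calls of *AXIN2*, *NDUFS3* and *TIPARP* were lost without each of the 3 pairs, that of *AXIN2* with either other scaling, those of *NDUFS3* and *TIPARP* with the mean over regions (changes -0.08 and -0.16), and that of *CYP1B1* without pair 1 or pair 3.

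**Figure D3:**
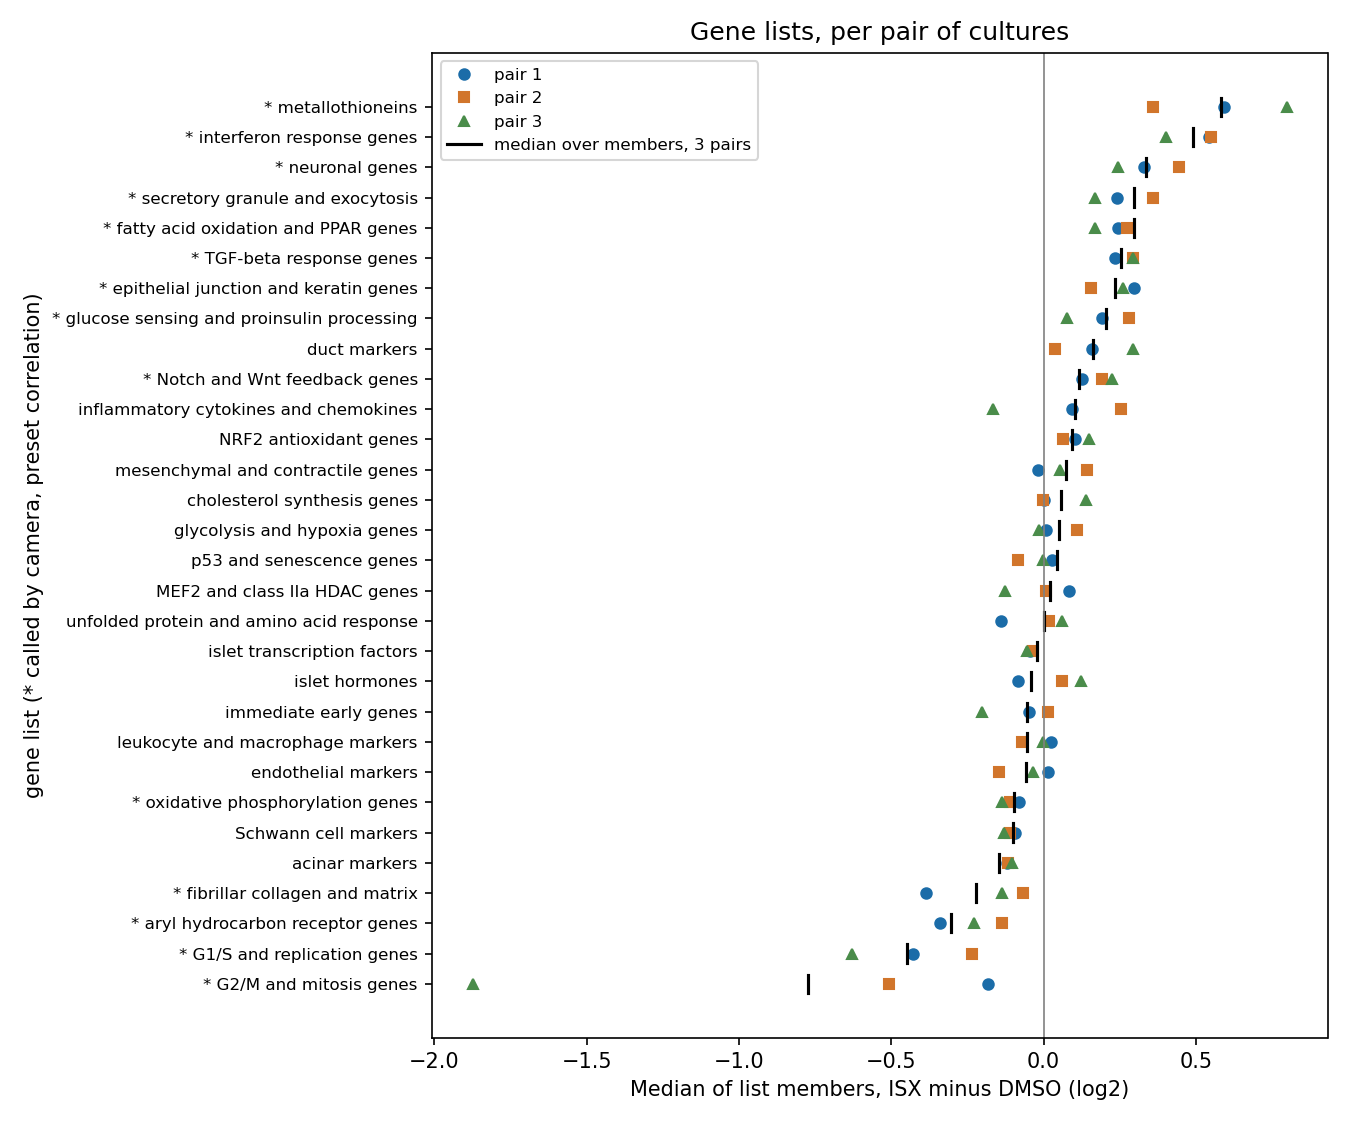
Median change of the measured members of each of the 30 gene lists (x axis, ISX minus DMSO, log2 units) in pairs 1 to 3 (symbols), with a bar at the median over members of the change fitted on all pairs. Lists (y axis) with a star passed camera at its preset correlation. The G2/M and mitosis list spans -1.87 to -0.18 between pairs.

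None of the remaining lists passed camera over all 3 pairs, and single members changed in both directions. Of 14 NRF2 antioxidant genes 3 rose, 4 adjusted over the list alone: *ME1* by 0.90, *PIR* by 0.81 and *NQO1* by 0.48 (list adjusted p = 0.0545, but 0.0261 without pair 2, 0.0479 with quantile normalization and 0.0425 with the mean over regions). *AKR1C1* had a change of 0.39 and passed adjusted over the list alone, and over all genes with the mean over regions (change 0.78, adjusted p = 0.0234). With that gene value *PIR* and *NQO1* rose by 0.51 and 0.32. Of 26 inflammatory cytokine and chemokine genes 4 rose, also adjusted over the list alone: *CCL20* by 0.97, *IL33* by 0.81, *MMP3* by 0.68 and *IL6* by 0.45 (list adjusted p = 0.105, but 0.00175 without pair 3 and 0.00807 with the mean over regions, where *CCL20* and *IL6* rose by 0.56 and 0.29). Of 28 immediate early genes *BTG2* rose by 0.31, and *FOSL1*, *NR4A1* and *IER3* fell by 0.67, 0.58 and 0.38. Adjusted over the list alone 1 rose and 4 fell (list adjusted p = 0.220). Of 16 cholesterol synthesis genes *STARD4* rose by 0.81 and *DHCR7* by 0.53, also adjusted over the list alone (list adjusted p = 0.202). The calls of *CCL20*, *MMP3* and *IL6* were lost without pair 1, those of *IL33* and *IL6* without pair 2, those of *NR4A1* and *IER3* without pair 1 or pair 3, and that of *BTG2* without each pair, with either other scaling and with the mean over regions (change 0.14). Without pair 3 the change of *NR4A1* was -0.38.

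Of 23 glycolysis and hypoxia genes 3 rose and 1 fell, also adjusted over the list alone. *EGLN3* rose by 0.99, *ALDOC* by 0.63 and *PFKFB3* by 0.38, and *VEGFA* fell by 0.61 (list adjusted p = 0.319 by camera). Of 19 genes of the unfolded protein and amino acid response 2 rose and 3 fell, and 2 rose and 4 fell adjusted over the list alone. *SLC7A11*, a cystine transporter, rose by 0.95, and *SESN2*, *TRIB3* and *XBP1* fell by 0.53, 0.49 and 0.40 (list adjusted p = 0.914). The median of this list was 0.0004 and its mean -0.005. Of 19 p53 and senescence genes 3 rose and 1 fell, and 4 rose and 5 fell adjusted over the list alone. *CDKN2B*, an inhibitor of cyclin-dependent kinases, rose by 0.76 and *RRM2B* by 0.47 (0.28 with the mean over regions), and *FAS*, a death receptor, fell by 0.44 (list adjusted p = 0.823). Of 7 MEF2 and class IIa histone deacetylase genes *MEF2C* and *HDAC9* rose by 0.45 and 0.42 and *MEF2D* fell by 0.28, also adjusted over the list alone (list adjusted p = 0.823). The calls of *MEF2C*, *HDAC9* and *MEF2D* were lost without each pair, those of *MEF2C* and *HDAC9* also with either other scaling, and those of *PFKFB3*, *FAS* and *XBP1* without 1 pair or more. With the mean over regions the changes of *MEF2C*, *HDAC9*, *MEF2D* and *PFKFB3* were 0.25, 0.23, -0.16 and 0.12, and the last 2 were not called. Without pair 2 the immediate early and duct lists passed camera (adjusted p = 0.0174 and 0.0267). The islet hormone and islet transcription factor lists had adjusted p of 0.912 and 0.887.

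In all, 14 of 30 lists passed camera with the preset correlation, 9 higher and 5 lower. None passed with an estimated correlation (3 had an unadjusted p under 0.05). That form of camera uses the few residual degrees of freedom of 6 arrays, so few lists could pass it. The estimated correlation ran from -0.0735 to 0.953 over the 14 lists, with 3.45e-05 for secretory granules, -0.0296 for neuronal and -0.0128 for epithelial genes. It was 0.953 for mitosis, 0.455 for metallothioneins, 0.397 for matrix and 0.321 for replication genes, far above the preset 0.01. For these lists the p-values with the preset correlation may be far too small. Other divisions of the 6 arrays into 3 and 3 gave up to 11 lists with the preset correlation. With the pair block they still hold the treatment difference of 1 pair or more, so they give no chance count. Of the 14 lists, fry, which tests whether a list moves one way on balance, called 10, and the acinar list besides, and left out both cell division lists, the matrix list and the metallothioneins.

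Within many genes, regions changed by unequal amounts. In *CYFIP2*, which acts on actin through the WAVE complex, the 61 regions changed by -0.25 to 4.44 (log2), with a median of 2.07, and 28 regions lay above and 24 below the rest of the gene. Of 18594 genes with at least 3 regions, 4351 showed unequal change by limma's diffSplice at an adjusted p under 0.05. Of 380509 regions, 18451 changed relative to the rest of their gene, 9026 upward and 9425 downward. Among the 4351 genes, 2321 were not called at the gene level.

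The other 5 of the 6 genes with the smallest p were *HLA-DPA1*, *HLA-F*, *HLA-DOA*, *HLA-DPB1* and *HLA-DMA*, which present or help to load antigens. Their regions repeat on the array: *HLA-DPA1* had 191 regions, of which 32 held distinct values. The gene-level changes were 1.95 for *HLA-DPA1*, 0.85 for *HLA-DMA*, 0.68 for *HLA-F* and 0.41 for *HLA-DOA*, which rose (that of *HLA-DOA* was not called without any 1 of the pairs or with either other scaling), and 0.39 for *HLA-DPB1*, with an adjusted p of 0.0578 by limma. With the mean over regions *HLA-DPB1* passed (change 0.58, adjusted p = 0.0024) and *HLA-DPA1* rose by 1.17. With repeated regions left out, a choice made after the values were seen, *CYFIP2* was followed by *MIAT*, *L1CAM*, *ABI3BP*, *KIF1A* and *PTPRN*. Regions of *L1CAM*, a neuronal adhesion molecule, changed by -0.39 to 4.20, and those of *KIF1A*, a motor of axonal transport, by -0.31 to 4.08. Regions of *PTPRN* changed by -0.37 to 3.05.

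The test uses 1 variance for all regions of a gene, and with the same contrast and a variance for each region (a test chosen after seeing the data) 2946 regions passed, 2879 of them among the 18451. Without the pair block 4141 regions in 1427 genes passed, and without pair 1, 2 or 3 the counts were 12144, 11355 and 10401 regions.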

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

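The 3 results in this part come from regions outside the gene test and were chosen for display after their values were seen.

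Of 36 regions annotated jointly to INS, IGF2 and INS-IGF2, 11 were higher and 0 lower with ISX than with DMSO, with a median change of 0.19 (log2) over all 36 and of 1.42 among the 11. Without pair 2 the median of the 11 was 0.84, and without the pair block none of the 36 passed. The 3 regions of this locus with a mean of at least 10 that did not pass changed by 0.08 to 0.14, and no region can be assigned to 1 of the genes here. The 11 had medians of 9.78, 7.20 and 8.61 in DMSO cultures 1 to 3. Some other regions were far lower in DMSO culture 3, as *GCG* was. Of these, 1 stood at 11.2, 11.0 and 5.78 and changed by 0.33, and another at 9.74, 9.70 and 5.43 and changed by -0.18. Neither passed, so the 11 cannot be read as a rise of INS. Of 164498 regions without a gene symbol, 3688 were higher and 2000 lower with ISX (3212 and 3274 with equal array medians), and 1234 were at least 2-fold higher with ISX than with DMSO and 103 at least 2-fold lower. Of 22452 regions with several symbols, 880 were higher and 1119 lower with ISX (770 and 1648 with equal array medians), and 326 were at least 2-fold higher and 130 at least 2-fold lower. Without the pair block 479 regions without a symbol were higher and 37 lower, and 166 and 34 of those with several symbols. Without pair 1 these counts were 1802 and 455, and 509 and 380. Without pair 3 the regions without a symbol were 2753 higher and 1136 lower, and those with several symbols 679 and 645. Without pair 2 and without pair 3, 254 and 210 regions without a symbol were at least 2-fold lower.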

How the results depend on the processing

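Without the pair block 634 genes passed, against 3040 with it, and 4141 regions in 1427 genes, against 18451 in 4351. All 634 were among the 3040. Without the block the list count was 11. Leaving out pairs gave 1825 to 1930 genes (1825, 1929 and 1930 without pair 1, 2 and 3), of which 1701, 1763 and 1799 were among the 3040. It gave 10401 to 12144 regions (12144, 11355 and 10401) and 2642 to 2825 genes with unequal regions (2825, 2783 and 2642), where fewer samples leave less power. The mean over regions in place of the median gave 5220 genes, with 54.5% higher, and the cause was not tested. The plain paired test, with 2 degrees of freedom, called 0 genes after adjustment and 4086 at an unadjusted p under 0.05. A 2-fold change with an unadjusted p under 0.05 and no block called 486 genes, 477 of them higher. The other alternatives gave 2215 to 4451 genes, within 1.5 times of the main count. With an estimated correlation, which leaves few degrees of freedom, camera called 0 lists (3 at an unadjusted p under 0.05), and fry called 11. In the other list settings 10 to 17 lists passed. Only bright regions of bright genes gave 9412 regions in 2742 genes from fewer regions tested, and with junctions 28876 regions passed. Leaving out duplicated regions, chosen after seeing the data, gave 17783, and a variance for each region with the same contrast, also chosen then, gave 2946, of which 2879 were among the 18451. With region minus gene median as well, which changes 2 choices, 623 passed, of which 580 were among the 18451. In simulated data with independent regions, diffSplice made more false calls where regions of a gene differed in spread (60 genes against 12). Where regions differed in spread and also shared variance, 8 genes were false. With another scaling or gene value no list and no named gene that passed in either setting changed its direction. The medians of 3 lists that did not pass camera (MEF2 and HDAC, unfolded protein, p53) changed sign with another scaling. Dim genes near the array's floor can show little fall, which limits what can be said of them.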

Other observations

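The tests of gene families in this part, the scaling test of 2-fold changes, the look at control features, the tests of islet hormone and transcription factor genes and the counts over other divisions of the arrays were chosen after the results were seen. Genes were grouped by the stem of their symbol into 340 families of 8 to 150 genes, and 14 families passed camera with the preset correlation, whereas with an estimated correlation the adjusted p of each of the 14 was 0.783. Of 13 GALNT genes, whose enzymes start mucin-type glycosylation, 8 rose (median 0.63). Of 18 PCDHB genes, clustered protocadherins of neurons whose sequences are similar and whose single values are uncertain, 9 rose (median 0.61). Of 12 SCN genes, subunits of sodium channels, 5 rose (median 0.38), and of 20 SEMA genes, guidance cues of axons, 9 rose (median 0.24). Of 18 SYT genes 7 rose (median 0.27), and of 11 MCM genes, which overlap the replication list, 6 fell (median -0.42). The other families that passed were PSG, EPB, TSPAN, ITGA, DOCK, IFI, TLR and FNDC. Their medians ran from 0.14 for FNDC to 0.77 for PSG, the largest of the 14. With quantile normalization and with equal array medians the medians of all 14 families kept their sign.

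More genes rose than fell with ISX (2147 against 893). A floor of dim genes may hide falls: above the median gene level 65.7% of the called genes were higher, but the share was 82.2% up to the median, 75.1% from there to the 75th percentile and 58.3% above it, so the median was too low a limit for this test and the floor stays open. With the array medians set equal the share higher was 54.7%, and 60.1% with quantile normalization, so array scaling may account for part of the excess. ISX arrays scaled too high would give control values above 0. In pairs 1 to 3, 1343 control features with numeric names had median changes of -0.06, -0.06 and -0.10, and 155 ERCC features of 0.004, -0.06 and -0.07. For 32 other controls these were 0.07, 0.01 and -0.04. The median change of all genes was -0.04. It was -0.09 with equal array medians and -0.06 with quantile normalization, so both scalings moved it further below 0. The controls differ in sign, so scaling stays open. Among called genes changed at least 2-fold, 95.7% were higher with equal array medians. The median gene of the DMSO and ISX array was 6.30 and 6.35, 6.38 and 6.42, and 6.36 and 6.42 in pairs 1 to 3. Setting such close medians equal could hardly alter this share, so the test was bound to give a high value. A shift of that size is too small for 2-fold changes, and a larger one was not tested. The 10 divisions of the 6 arrays into 3 and 3 are too few for a share under 0.05: 1 gave as many genes, the real one with 3040, and the highest of the others had 0, also among the divisions that part all 3 pairs. With the pair block the other divisions still hold the treatment difference of 1 pair or more, as effect and as spread. They therefore give no chance count, here or below.

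Of 27 neuronal, 30 secretory granule and 17 epithelial genes 11, 9 and 8 rose, each list had adjusted p = 0.346 with an estimated correlation, and of the 10 divisions of the arrays, too few for a share under 0.05, 1, the real one, gave as many lists, 14 against 11 in the highest other and 7 among the others that part all 3 pairs. These other divisions still hold part of the treatment difference, so their 11 and 7 lists are no chance count. More islet endocrine cells of every kind, or fewer of the cells around them, would raise all their transcripts. The 12 islet hormone and transcription factor genes above the median gene had a median change of -0.0637 against 0.297 for the granule list. The 95% bootstrap interval, drawn over these genes and not over cultures, was -0.184 to -0.0038. Only SST of the 12 lay above the 75th percentile. The others may lie too close to background to show a rise, so this median cannot decide the question. Of the hormones abundant in pairs 1 and 2 GCG had a change of -0.77 there (95% interval -0.99 to -0.54), SST of 0.09 (-0.13 to 0.30) and IAPP of 1.23 (0.49 to 1.98, from 0.36 and 2.11 in the pairs), so they moved apart. For pairs 1 and 2, more endocrine cells of every kind or fewer cells around them would not alone move these hormones apart. Such a change in cell share beside a response of the cells to ISX was not excluded. The limit used was set after the values were seen, when a first one, that each lie below 0.297, had decided nothing. Its outcome was thus known in advance. More beta cells alone may still contribute, since IAPP had a change of 0.855 over all pairs (95% interval 0.062 to 1.65), but 0.23 without pair 2. In pair 3 IAPP was low, at 2.82 with DMSO and 2.92 with ISX, where the 25th percentile of genes was 4.70 and 4.74. The granule, neuronal and epithelial lists had median changes of 0.169, 0.245 and 0.261 in that pair. IAPP may lie too close to background in pair 3 to show a rise beside that of the lists, and this is 1 pair, so it does not decide the question. INS was not measured alone, so more beta cells as an explanation stay open. Regions that cross-react could also raise such genes: the median junction change of 27 called members was 0.754 of that of their regions (interval 0.445 to 1.16), with a rise in 27 of 27, so cross-reaction as the whole cause was not excluded by the limit set, and a response of these cells to ISX stays open too.

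Regions of one gene changed unequally in 4351 genes. The share of such genes was 4.63 times higher among genes called at the gene level (68.7%) than among the others (14.8%), so regions that do not respond, in genes whose overall level changed, are a candidate explanation for many of them. Without regions of duplicated values 98.8% of the count was left, so regions with identical values do not account for most of these genes. Such regions were only 3.74% of the regions with 1 symbol, so a large drop was unlikely in advance. Probes shared by regions with unlike values were not tested. Of the 10 divisions 1, the real one, gave as many genes, 4351 against 100 in the highest other and 12 among the others that part all 3 pairs, and 10 are too few for a share under 0.05. The others still hold part of the treatment difference, so they give no chance count. Regions of unequal spread may also add calls, since with the same contrast and a variance for each region 2946 of 380509 regions passed, but that test has fewer degrees of freedom and lower power may account for part of the drop, and altered splicing was not tested.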
